A study of Mus musculus with 19 samples.

How the data were processed

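Gene expression and chromatin accessibility were measured in 2 kinds of blood progenitor, each sorted from the liver of C57BL/6 mouse embryos at embryonic day 14.5 and from the bone marrow of mice aged 12 weeks. HSC are hematopoietic stem cells, sorted as cells with c-Kit, Sca-1 and CD150 on their surface and without CD48, Flt3 and markers of mature blood cells. LMPP are lymphoid-primed multipotent progenitors, sorted as cells with c-Kit, Sca-1, CD48 and Flt3 and without CD150. The adult gates also left out cells with CD11b, the product of Itgam, and the labels do not say whether the fetal gates did. RNA-seq covered 11 libraries: 3 of adult HSC, 2 of fetal HSC, 3 of adult LMPP and 3 of fetal LMPP. ATAC-seq, in which a transposase tags open chromatin, covered 8 libraries, 2 in each of the 4 groups. The labels do not say that replicates came from separate animals or pools, so p-values measure the spread between these samples, which may be technical.

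RNA was made into cDNA with an oligo-dT template-switching kit and tagmented, per the labels' protocols, and this chemistry keeps neither strand nor molecular identifiers. The deposited table holds the authors' expected counts of reads in exons, 1 line per gene named by a RefSeq transcript and a symbol, made with HOMER on mm10 without normalization, per the file headers. Its values move in steps of 0.5 (22.5% of values are not whole), so they were rounded to whole counts before testing. The table holds 25124 genes, of which 20870 are protein coding, and 0 of its columns belong to other libraries. Trim Galore, STAR, RSEM, HOMER, DESeq2, Bowtie2 2.3.5, Picard, SAMtools 1.9 and MACS2 appear in the submitters' processing notes, with the builds mm10, NCBIM37 and GRCm38.p5 and without roles. Genes with near-identical copies (the H2-Q, hemoglobin, histone and ribosomal protein genes), overlapping genes and antisense partners can share reads, so their single values are uncertain.

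For accessibility, 1 list of reproducible peaks per group was used, each made by the authors from the 2 replicates of the group, with coordinates in mm10. In each list the deposited score of a peak, its signal value from the authors' peak caller, and its −log10 p and q values were taken as the authors gave them and used only to describe, rank or filter peaks within that list. Whether reads of replicates were pooled before the final call is not given in the sources used here. Lines of a list that describe several summits of the same peak were merged into distinct peaks. With 1 list per group, accessibility has no spread between replicates, so no region was tested for a difference between groups, and tests on regions compare numbers of genes or regions only.

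Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were left out with filterByExpr, which kept 14720 genes, and libraries were scaled by TMM. A means model of the 4 groups over all 11 libraries was fitted by quasi-likelihood, with a common biological coefficient of variation of 0.372 and 3.46 prior degrees of freedom. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Comparisons were fetal against adult HSC, fetal against adult LMPP, LMPP against HSC at each age, and the difference of the fetal against adult differences between HSC and LMPP (the interaction). Values are counts scaled to a common library total (CPM) as mean ± SD over libraries, and log2 differences are given ± SE. Every adjusted p of a gene is from edgeR, and of a list from camera, unless another tool is named. Library totals ran from 19.8 to 64.8 M counts, so 3 counts, the limit that a count of 0 allows, are worth 0.0498 to 0.152 CPM per library. Folds against a group with all libraries at 0 are lower bounds at this floor of 3 counts per library. Floors cover counting error only, since reads copied by PCR without molecular identifiers are not independent molecules. Fitted log2 values of such genes depend on the prior count, so list medians are also given with these members at their bound where that differs.

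Before the data were examined, 23 gene lists, 9 lists of markers of other cell types (hepatocytes, endothelial and stromal cells, macrophages, neutrophils, B cells, T and NK cells, mast cells with basophils and eosinophils, erythroblasts, and sex-linked genes) and the rule for named genes were fixed from textbook knowledge. Named genes were the 8 largest rises and 8 largest falls among called genes with a mean of at least 5 CPM and no overlap between the libraries of the groups, leaving out predicted and clone-named genes, the 3 members with the lowest p of each called list, and 18 fixed genes. For the interaction they were the 6 largest values in each direction, without the overlap condition, and the fixed genes. Some genes that this rule names are not reported here. The symbols Gpr56, Ighm, Igj, Cyr61, Ighd, Trbc1, Trbc2 and Ahsp found no match in the table. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 23 lists of a comparison, and called at an adjusted p under 0.05. Camera with an estimated correlation and fry, which tests a list against no change, served as alternatives. Marker sums without 1 gene were added after seeing the data. Over all comparisons, 10 of the 73 list calls held with an estimated correlation, and its adjusted p is given beside each list.

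Peaks of the lists compared were merged where they shared at least 1 bp, in Python 3.11.15 with scipy 1.17.1. A region counted as a promoter region within 1000 bp of a start site, and regions were given to the nearest gene with a start site within 50000 bp. Fisher's exact tests, two-sided, were run across regions or genes, which are not independent replicates. Motif content was not analysed here.

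Other settings tried were DESeq2 1.42.0, RLE factors, library totals only, no filter, a stricter filter (at least 1 CPM in 3 libraries and 50 counts in all), a fit of only the 2 groups compared, a replicate block, leaving out each library, a prior count of 0.5, stricter peak lists and other distances. Added after seeing the data were a term for 3 libraries that stand apart, a fit without them, and a fit of the 6 adult libraries with the replicate number as a block. Deviations of same-numbered adult HSC and LMPP libraries from their group means correlated across genes at 0.15, 0.31 and 0.47. The 0.47 is for libraries that stand apart, so pairing was not shown. Other comparisons gave lower values.

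Each step was tested on simulated data for 14720 genes with 100 genes changed by each fold. At a 2-fold change the test recovered 9% of genes for fetal against adult HSC, 23% for fetal against adult LMPP, 17% for adult LMPP against HSC, 8% for fetal LMPP against HSC and 0% for the interaction. At a 4-fold change it recovered 60%, 73%, 67%, 61% and 33% in the same order, with 2, 7, 6, 1 and 0 false calls. A list shifted on purpose was always called, with 0 of 22 others, but correlation between genes was not simulated. A gene not called was not shown equal between groups.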

Results

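Gene expression was measured in HSC and LMPP of the fetal liver and the adult bone marrow, in 11 RNA-seq libraries. The series set fetal against adult cells under a title on developmental signals and emergency megakaryopoiesis, the rapid making of platelet precursors under stress. Library totals were 28.82, 27.44 and 61.67 M counts for adult HSC 1 to 3, 23.71 and 37.52 for fetal HSC 1 and 2, 19.8, 34.95 and 33.12 for adult LMPP 1 to 3, and 64.78, 29.37 and 24.92 for fetal LMPP 1 to 3. Open chromatin was described by 4 peak lists, 1 per group. Gene positions are in mm10.

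The libraries separated by cell type and by age. The first principal component of log2 CPM held 43.1% of the variance and parted HSC from LMPP, and the second held 23.2% and parted adult from fetal cells. Within groups, libraries correlated across genes at 0.934 to 0.977 (Pearson), and between groups at 0.829 to 0.927. On component 3, with 10.4% of the variance, adult HSC 3 (−89.1), fetal LMPP 1 (−57.5) and adult LMPP 3 (−24.5) lay apart from the other libraries of their groups. Ubb, a ubiquitin gene, took 2.68% and 2.59% of counts in adult HSC 3 and adult LMPP 3, against 0.897% to 1.54% in the other 9 libraries. Counts of genes are therefore also given without these 3 libraries, a fit chosen after seeing the data.

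**Figure D1:**
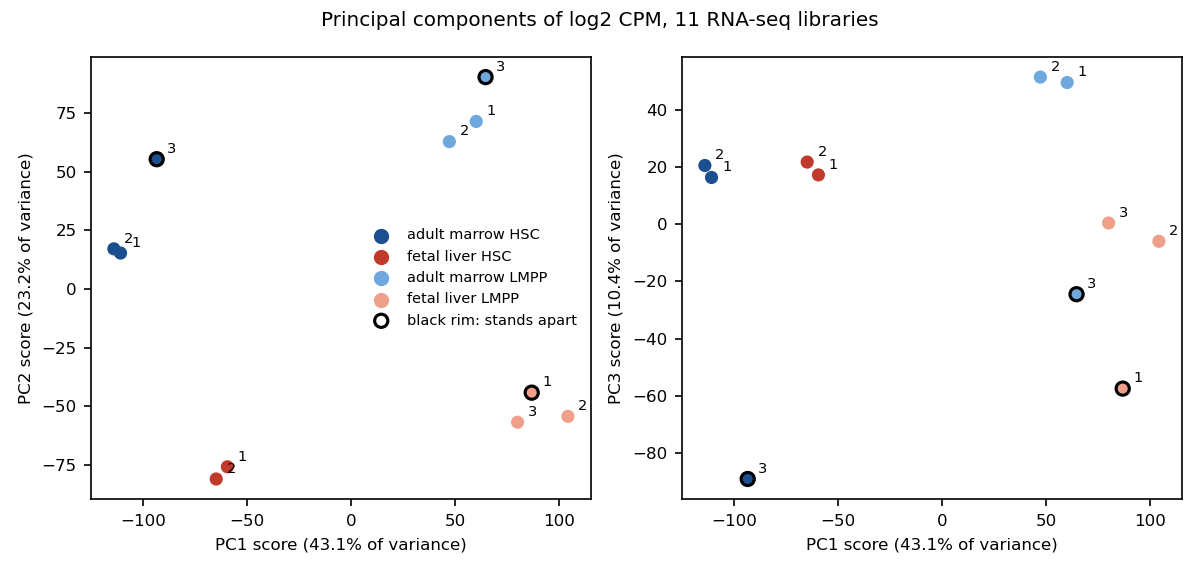
Principal component scores of log2 CPM for the 11 RNA-seq libraries, component 1 against 2 (left) and 1 against 3 (right), with 1 point per library, colour for the group, digits for the replicate and a black rim for the 3 libraries that stand apart. HSC and LMPP part on the first component (43.1% of variance), fetal and adult cells on the second (23.2%), and adult HSC 3 lies at −89.1 on component 3 (10.4%).

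The first comparison asked how HSC of the fetal liver differ from HSC of the adult marrow (n = 2 and 3 libraries). Fetal HSC held far more RNA of fetal growth regulators. Lin28b, an RNA-binding protein that blocks let-7 microRNAs (chromosome 10, 45376619 to 45470201), stood at 25.3 ± 6 CPM in fetal and 0.379 ± 0.359 CPM in adult HSC (log2 6.11 ± 0.66, adjusted p = 0.0013). Igf2bp1, an mRNA-binding target of let-7 (chromosome 11, 95957164 to 96005944), was at least 937-fold higher (75.8 ± 1.59 CPM against 0 in all adult libraries, adjusted p = 0.00013). Adult HSC held more RNA of antigen presentation genes. The retinaldehyde dehydrogenase Aldh1a1 (chromosome 19, 20492583 to 20643463) was at least 1250-fold lower in fetal HSC, at 0 against 120 ± 19.6 CPM (adjusted p = 0.0032). H2-Aa, an MHC class II chain (chromosome 17, 34282744 to 34287823), fell from 74.2 ± 33.2 to 0.217 ± 0.141 CPM (log2 −8.30 ± 1.19, adjusted p = 0.0026).

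In all, 304 genes were higher and 425 lower in fetal HSC by edgeR, of which 251 and 365 differed at least 2-fold. Without the 3 libraries that stand apart the counts were 1096 and 1241, and with a term for them 956 and 967. Leaving out fetal HSC 1 left 137 and 132 genes, and leaving out fetal HSC 2 left 104 and 109. Other large rises were Postn, a matrix protein (at least 291-fold, 23.5 ± 5.93 CPM against 0), Id3, an inhibitor of basic helix-loop-helix factors (log2 6.31 ± 0.43), Crispld2 (5.83 ± 0.91) and Pik3r6 (5.78 ± 0.70). Among the large falls, Sult1a1, a sulfotransferase, fell by 7.87 on the log2 scale (± 0.95). Aspa was at 14.7 ± 4.09 CPM in adult HSC and had 0.0197 CPM in fetal HSC. Myl10, Clec1a and Gda fell (log2 −7.60, −7.19 and −7.18). Myl10 was uneven among adult libraries (65.2 ± 62.7 CPM). The calls of Aspa and Myl10 ended without fetal HSC 1 (adjusted p = 0.069 and 0.05) or fetal HSC 2 (0.12 and 0.065), and that of Crispld2 with only these groups compared (0.058). That of Clec1a ended with DESeq2 (0.079), with a replicate block (0.059), and without adult HSC 2 (0.054) or fetal HSC 2 (0.064). That of Gda ended with the block (0.057) and without adult HSC 1 (0.081), adult HSC 2 (0.11), fetal HSC 1 (0.084) or fetal HSC 2 (0.23). Clec1a and Gda were at 0 in fetal HSC without fetal HSC 1, where their fitted values moved by over 1.5 times.

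Of 17 tested genes of the Lin28b and let-7 list, 6 rose in fetal HSC (7 adjusted over the list alone; median log2 1.60; adjusted p = 3.66e-09, and 0.043 with an estimated correlation). Besides Lin28b and Igf2bp1 they included Igf2bp2 (222 ± 25.1 against 15.6 ± 3.89 CPM), Igf2bp3 (80.4 ± 1.25 against 2.13 ± 0.932 CPM), and the chromatin proteins Hmga1 (594 ± 36 against 153 ± 13.4 CPM) and Hmga2 (120 ± 15.7 against 2.89 ± 1.28 CPM). Among 23 imprinted genes, expressed from a single parental allele, H19, Igf2, Dlk1 and Slc38a4 rose and Phlda2 fell (5 and 1 over the list alone; median 0.73; adjusted p = 0.000194, and 0.082 with an estimated correlation). The list median was 0.47 without fetal HSC 2. H19, a noncoding RNA, stood at 73.3 ± 13.3 against 0.158 ± 0.12 CPM, the growth factor gene Igf2 at 35.3 ± 6.83 against 0.538 ± 0.348 CPM, and Dlk1 at 80 ± 21.6 against 3.77 ± 0.165 CPM.

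Antigen presentation genes fell together: 17 of 20 (19 over the list alone), with a median of −2.35 (adjusted p = 1.48e-27, and 0.039 with an estimated correlation). The nonclassical MHC gene H2-T23 fell from 417 ± 29.4 to 105 ± 9.82 CPM, and H2-Q6 and H2-Q7, which are close copies, fell (log2 −5.55 and −5.23). Of 47 interferon response genes 15 fell (21 over the list alone; median −0.75; adjusted p = 7.91e-10, and 0.082 with an estimated correlation). The peptide transporter Tap1 was at 72.8 ± 1.04 against 224 ± 22.9 CPM and Ifi27 at 20.1 ± 1.18 against 71.7 ± 13.7 CPM. Among 25 inflammatory genes Nfkbia, Il18, Ccl3 and Cd69 fell (5 over the list alone; median −0.19; adjusted p = 0.0168, and 0.082 with an estimated correlation). Nfkbia, the inhibitor of NF-kappaB, went from 144 ± 12.4 to 49.1 ± 7.04 CPM. This list call ended without adult HSC 2 (adjusted p = 0.087), and its median was −0.39 without adult HSC 3, −0.37 without fetal HSC 2 and −0.41 without the 3 libraries that stand apart. The call of Ccl3 ended in 5 alternatives (0.052 to 0.21), among them those without fetal HSC 1 (0.17) or fetal HSC 2, and that of Il18 without fetal HSC 2 (0.091).

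The megakaryocyte and platelet list lay lower in fetal HSC, with a median of −0.90 (adjusted p = 0.00011, and 0.17 with an estimated correlation). Of its 30 tested genes, 3 fell (10 over the list alone, and 13 over all genes without the 3 libraries that stand apart). Without fetal HSC 1 the list median was −1.49. Pf4, a platelet chemokine (chromosome 5, 90772435 to 90773383), stood at 17.8 ± 12.1 CPM in fetal and 284 ± 218 CPM in adult HSC (log2 −4.00 ± 0.88, adjusted p = 0.027). The tetraspanin Cd9 fell from 305 ± 82.3 to 84.1 ± 0.18 CPM (adjusted p = 0.0019) and the chaperone gene Clu from 79.1 ± 15.1 to 17 ± 10.3 CPM (adjusted p = 0.026). The Pf4 call ended with only these groups compared (adjusted p = 0.053) and without adult HSC 1 (0.06), fetal HSC 1 (0.1) or fetal HSC 2 (0.25), and that of Clu without adult HSC 1 (0.051), adult HSC 2 (0.054) or fetal HSC 2 (0.24), or with the replicate block (0.06). Itga2b, the integrin CD41, at 73.2 ± 33.4 against 474 ± 251 CPM (adjusted p = 0.075), Vwf (adjusted p = 0.57) and Selp (adjusted p = 0.93) did not pass, while Itga2b and Vwf passed without the 3 libraries that stand apart (0.0021 and 0.016).

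Hemoglobin genes were higher in fetal HSC: 4 of 8 rose, also over the list alone (median 4.63, or 4.56 with members at 0 at their bound; adjusted p = 9.55e-07, and 0.082 with an estimated correlation). Hbb-bt was at 633 ± 65.2 against 18.8 ± 5.37 CPM, Hbb-b1 was at 309 ± 14 against 14 ± 6.93 CPM, and the beta-globin genes share reads with their copies. The erythroblast markers, which hold several of these genes, summed to 1310 ± 108 against 104 ± 69.9 CPM, while the erythroid lineage list was not called (adjusted p = 0.748), with 1 of 21 genes lower by edgeR, 5 by DESeq2 and 3 over the list alone. Lymphoid priming genes had a median of 0.58, or 0.50 at the bound (adjusted p = 0.00142, and 0.082 with an estimated correlation), and 5 rose, among them Cnn3, Flt3, Wfdc17 and Satb1 (11 of 28 over the list alone). Satb1, a chromatin organiser, was at 27.3 ± 4.62 against 4.43 ± 1.95 CPM, Cnn3 at 193 ± 5.47 against 9.18 ± 2.88 CPM and Wfdc17 at 28.1 ± 2.98 against 2.18 ± 1.23 CPM. The lymphoid median was 0.22 without fetal HSC 2.

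Further lists were called with the preset correlation only. Mitosis genes had a median of 0.38 (Ect2 and Kif23 rose, 2 over the list alone; adjusted p = 4.26e-05, and 0.52 with an estimated correlation). Ect2, a factor of cell division, rose from 31.7 ± 1.83 to 98.6 ± 23 CPM. Histone genes had a median of 0.50 (Hist1h1c rose, 7 over the list alone; adjusted p = 0.0013, and 0.39 with an estimated correlation). Cholesterol synthesis genes lay at −0.50 (Idi1 fell, 4 over the list alone; adjusted p = 0.00263, and 0.22 with an estimated correlation). Ribosomal protein genes lay at 0.16 (adjusted p = 0.00284, and 0.56 with an estimated correlation), with 0 of 54 genes called by edgeR, 9 at an unadjusted p under 0.05 and 3 called by DESeq2. The Hoxa and Hoxb genes lay at 0.52 (adjusted p = 0.0466, and 0.41 with an estimated correlation), with 0 of 15 called by edgeR, 2 at an unadjusted p under 0.05 and 0 called by DESeq2. The list calls of ribosomal proteins (adjusted p = 0.056) and of Hox genes (0.13) ended without adult HSC 1, and that of Hox genes also without fetal HSC 2 (median 0.25, 0.22), with a stricter filter (0.16), with DESeq2 (0.23) and with only these groups compared (0.078). Mitosis genes had medians of 0.15 and 0.63 without fetal HSC 1 and fetal HSC 2, and histone genes 0.14 without fetal HSC 1. The call of Kif23 ended without any 1 of the 5 HSC libraries (0.059 to 0.4), without a filter (0.054), with only these groups (0.17) and with the replicate block (0.086). That of Idi1 ended without adult HSC 2 (0.11), adult HSC 3 (0.068), fetal HSC 1 (0.27) or fetal HSC 2 (0.3), without a filter (0.052), with only these groups (0.13) and with the block (0.09). That of Hist1h1c ended without adult HSC 2 (0.061), adult HSC 3 (0.055), fetal HSC 1 (0.099) or fetal HSC 2 (0.26), with only these groups (0.079) and with the block (0.062). The lists for stem cells, granulocytes and monocytes, immediate early genes, heat shock, DNA replication, quiescence, ribosome biogenesis, oxidative phosphorylation and glycolysis were not called. Without the 3 libraries that stand apart, and with a term for them, the lists for DNA replication (0.0073 and 0.0043), quiescence (0.03 and 0.047), oxidative phosphorylation (0.00033 and 0.0029) and glycolysis (0.0089 and 0.0069) were called, quiescence lower (median −0.44 and −0.38) and the others higher (0.25 and 0.27, 0.23 and 0.19, 0.37 and 0.33).

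Itgam stood at 33.4 ± 5.25 CPM in fetal and 3.05 ± 1.17 CPM in adult HSC (log2 3.45 ± 0.42, adjusted p = 0.00096); the labels name its protein as gated out for adults and do not say whether fetal sorts left it out. Ly6a, which encodes Sca-1, fell by 1.67 (± 0.36, adjusted p = 0.024) and Flt3 rose by 1.12 (± 0.20, adjusted p = 0.0089). Without fetal HSC 1 these calls ended at adjusted p = 0.2 and 0.062, and without fetal HSC 2 at 0.2 and 0.095, while that of Ly6a also ended without adult HSC 2 (0.065) and with the replicate block (0.057), and with only these groups compared both ended (0.063 and 0.11). Kit, Slamf1 (CD150), Cd48, the stem cell genes Hlf and Procr, Mpo and Dntt did not pass (adjusted p = 0.97, 0.89, 0.075, 0.84, 0.7, 0.92 and 0.66), while Kit and Cd48 passed without the 3 libraries that stand apart (0.0038 and 0.0032). Markers of hepatocytes summed to 109 ± 63 CPM in fetal and 65.8 ± 17.2 CPM in adult HSC (44.1 ± 40.7 and 16.5 ± 6.78 without Trf; median fitted log2 4.82). Those of endothelial and stromal cells summed to 116 ± 21.1 and 29.9 ± 7.06 CPM (35.9 ± 0.496 and 26.2 ± 6.97 without the imprinted gene Dlk1), with Cdh5, Plvap and Dlk1 higher and Pdgfrb lower in fetal HSC. Sums for macrophages (36.4 ± 6 and 36 ± 19.5), neutrophils (9.53 ± 3.97 and 5.69 ± 6.1, Mmp9 higher), B cells (56.5 ± 10.4 and 52.6 ± 25.1), T and NK cells (14.4 ± 3.36 and 9.29 ± 2.29), mast cells with basophils and eosinophils (20.1 ± 23.4 and 50.2 ± 73.1) and sex-linked genes (186 ± 10.6 and 184 ± 30.6 CPM) stood close together or varied widely.

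**Figure D2:**
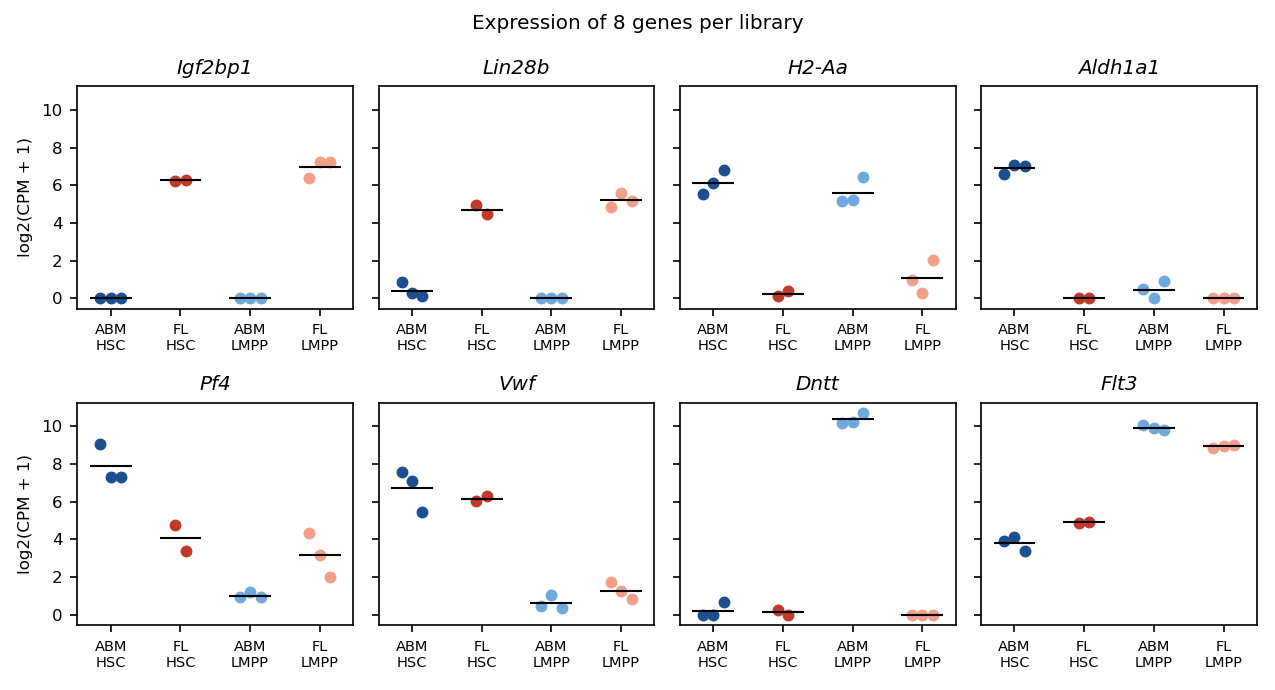
Expression of 8 named genes as log2(CPM + 1) on the y axis, with 1 point per library, the 4 groups on the x axis and a line at the mean of each group. Igf2bp1 and Lin28b sit high in both fetal groups (75.8 and 25.3 CPM in fetal HSC), Pf4 is highest in adult HSC (284 CPM), and Dntt is high in adult LMPP (1350 CPM) and at 0 in fetal LMPP.

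The same question was asked of LMPP (n = 3 and 3). Fetal LMPP lacked detectable Dntt, the polymerase that adds nucleotides to antigen receptor joins (chromosome 19, 41029275 to 41059525): it stood at 0 against 1350 ± 300 CPM in adult LMPP, at least 13900-fold lower (adjusted p = 0.00012). The same fetal regulators as in HSC were higher, with Igf2bp1 at 127 ± 39.2 CPM and Lin28b at 36.9 ± 10 CPM against 0 in every adult library (at least 1140-fold and 331-fold). Fetal LMPP held more RNA for ribosome biogenesis, and more of Ldha, lactate dehydrogenase (2730 ± 185 against 1100 ± 33 CPM). They held less RNA for antigen presentation, with H2-T23 at 60.9 ± 2.27 against 301 ± 33.3 CPM.

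In all, 1042 genes were higher and 1221 lower in fetal LMPP, 498 and 945 of them at least 2-fold. Without the 3 libraries that stand apart the counts were 2195 and 2215, and with a term for them 2666 and 2319. The count of higher genes dropped to 562 without adult LMPP 1, 682 without fetal LMPP 1, 617 without fetal LMPP 2 and 690 without fetal LMPP 3, and that of lower genes to 749 without fetal LMPP 2. Other large rises were Stc1, a secreted hormone (at least 262-fold), Col18a1, a basement membrane collagen (at least 257-fold), Zfp711 (at least 137-fold), Fscn1, an actin bundler (log2 6.85 ± 1.03), and Id1 (6.72 ± 0.38). Spats2 was at 13.4 ± 3.32 CPM in fetal and 0.0168 CPM in adult LMPP. Other large falls were Bpifc, the scavenger receptor Cd163 and Sdsl (at least 170-fold, 155-fold and 152-fold), the transporter gene Slc16a11 (log2 −8.66 ± 0.67), the hexokinase Hk3 (−7.50 ± 0.58), the guanylate-binding gene Gbp6 (−7.15 ± 0.88) and H2-Q5 (−7.10 ± 0.36).

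The list calls that held with an estimated correlation were led by antigen presentation, where 19 of 20 genes fell, also over the list alone (median −3.12; adjusted p = 7.66e-24, and 0.037 with an estimated correlation). H2-Q6 and H2-Q7 fell (log2 −6.14 and −6.11). Of 47 interferon response genes 30 fell (37 fell and 1 rose over the list alone; median −1.29; adjusted p = 1.4e-16, and 0.046 with an estimated correlation). Among them were Tap1 (56.6 ± 6.26 against 258 ± 16.5 CPM), Sp100, a nuclear body protein (31.5 ± 5.64 against 161 ± 8.73 CPM), and Lgals3bp (100 ± 16 against 285 ± 18.8 CPM). Of 17 genes of the Lin28b and let-7 list 8 rose (10 over the list alone; median 1.81; adjusted p = 9.83e-10, and 0.037 with an estimated correlation). Igf2bp2 was at 117 ± 16.8 against 2.71 ± 0.29 CPM, Igf2bp3 at 204 ± 9.48 against 2.73 ± 0.895 CPM, Hmga1 at 906 ± 49.1 against 208 ± 25.3 CPM and Hmga2 at 206 ± 70.6 against 11.8 ± 3.98 CPM. Of 35 ribosome biogenesis genes 16 rose (24 over the list alone; median 0.70; adjusted p = 8.33e-11, and 0.046 with an estimated correlation). Among them were the nucleolar genes Npm1 (1630 ± 242 against 773 ± 83.7 CPM), Ncl (1900 ± 127 against 947 ± 132 CPM) and Nop2 (257 ± 6.66 against 138 ± 9.13 CPM).

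Other list calls did not hold with an estimated correlation. Of 20 glycolysis genes 14 rose, also over the list alone (median 0.75; adjusted p = 1.12e-05, and 0.13 with an estimated correlation). Gapdh was at 1390 ± 65.9 against 726 ± 49 CPM and the glucose transporter Slc2a1 at 81 ± 6.24 against 32.4 ± 4.63 CPM. Of 49 oxidative phosphorylation genes 9 rose, also over the list alone, such as Atp5g3, Atp5b and Cox6b1 (log2 0.76, 0.68 and 0.64; list median 0.35; adjusted p = 4.14e-06, and 0.6 with an estimated correlation). Ribosomal protein genes had 11 rises and 1 fall (26 and 2 over the list alone; median 0.33; adjusted p = 1.12e-05, and 0.44 with an estimated correlation). Rpl29 and Rpl6 were up by 0.61 and 0.51. Imprinted genes had 9 rises and 1 fall (10 and 1 over the list alone; median 2.55, or 0.98 at the bound; adjusted p = 0.000129, and 0.11 with an estimated correlation). Dlk1 was at 62 ± 6.05 against 0.605 ± 0.431 CPM, H19 at 8.2 ± 0.374 CPM against 0 (at least 73.7-fold) and Snrpn at 10.6 ± 1.25 against 0.424 ± 0.157 CPM. Hemoglobin genes had 4 rises of 8, all of beta-globin copies, also over the list alone (median 3.09, or 2.59 at the bound; adjusted p = 0.000176, and 0.14 with an estimated correlation). Hbb-bt was at 128 ± 73.2 against 14.2 ± 2.78 CPM. Of 41 DNA replication genes 9 rose (13 over the list alone; median 0.22; adjusted p = 0.000392, and 0.51 with an estimated correlation), led by the cyclin Ccne1 (75.1 ± 4.89 against 21.7 ± 2.17 CPM), Mcm4 (0.54) and Mcm10 (1.05). The call of Mcm4 ended with library totals (adjusted p = 0.054) and without adult LMPP 1, fetal LMPP 1 or fetal LMPP 3 (0.062, 0.051 and 0.051), and that of Mcm10 without adult LMPP 3 or fetal LMPP 2 (0.052 and 0.056). The DNA replication median was 0.35 without adult LMPP 3, and that of imprinted genes 0.39 without fetal LMPP 2.

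Cholesterol synthesis genes had 3 rises, also over the list alone: Fdps, Sqle and Cyp51 (log2 0.83, 0.72 and 0.60; list median 0.50; adjusted p = 0.00223, and 0.21 with an estimated correlation). The call of Cyp51 ended with library totals (0.14), without a filter (0.062), with only these groups (0.076), with the replicate block (0.055), without adult LMPP 1 (0.17), adult LMPP 3 (0.12), fetal LMPP 1 (0.14), fetal LMPP 2 (0.069) or fetal LMPP 3 (0.13), and without the 3 libraries that stand apart (0.066). That of Sqle ended without adult LMPP 1 (0.057) or fetal LMPP 3 (0.053). Of 24 granulocyte and monocyte genes 7 fell (8 over the list alone; median −0.60; adjusted p = 0.0257, and 0.6 with an estimated correlation). Nkg7 was at 43.4 ± 7.8 against 299 ± 56.1 CPM, Plac8 at 305 ± 62.5 against 827 ± 59.6 CPM, and the receptor gene Csf2ra at 12.3 ± 1.99 against 26.9 ± 2.54 CPM. Inflammatory genes had 6 falls of 25 (7 over the list alone; median −0.17; adjusted p = 0.0417, and 0.13 with an estimated correlation). Il18, Relb and Nfkbia were down by log2 −2.56, −1.73 and −1.37. The calls of this last pair of lists ended without the 3 libraries that stand apart (adjusted p = 0.18 and 0.091), and without fetal LMPP 1 (0.055 and 0.086). The inflammatory call also ended without adult LMPP 2 (0.054) and with the term for the 3 libraries (0.067), and its median was −0.38 without adult LMPP 1 and −0.31 without fetal LMPP 2. The megakaryocyte list was not called (median 0.47, adjusted p = 0.0525, 0.024 by fry), although 8 of 30 genes were higher and 2 lower (9 and 2 over the list alone). Pf4 was at 10.2 ± 8.41 against 1.04 ± 0.27 CPM (adjusted p = 0.017), a call that ended without adult LMPP 1, adult LMPP 3, fetal LMPP 1 or the 3 libraries that stand apart (0.068, 0.057, 0.058 and 0.093).

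Flt3, a gate gene of LMPP, was lower in fetal LMPP (492 ± 21.7 against 974 ± 80.7 CPM, adjusted p = 0.0053), and Ly6a was lower too (19.3 ± 4.88 against 66.9 ± 16.8 CPM, adjusted p = 0.0041). Itga2b, Vwf, Selp, Itgam, Cd48, Kit, Mpo, Hlf, Procr and Slamf1 did not pass (adjusted p = 0.13, 0.23, 0.17, 0.57, 0.73, 1, 0.82, 0.48, 0.067 and 0.47), while Itga2b, Selp and Procr passed without the 3 libraries that stand apart (0.0045, 0.0059 and 0.0049). Hepatocyte markers summed to 119 ± 50.2 CPM in fetal and 260 ± 34.4 CPM in adult LMPP (40.1 ± 27.8 and 14 ± 1.98 without Trf; median fitted log2 7.23), with Alb, Apoa1 and Rbp4 higher and Trf, which these cells also express, lower in fetal LMPP. Erythroblast markers summed to 310 ± 196 and 42.4 ± 17.4 CPM, endothelial and stromal markers to 100 ± 8.56 and 48.5 ± 15.1 CPM (Dlk1 higher; 38.2 ± 9.53 and 47.9 ± 15.2 without it), macrophage markers to 17.5 ± 5.15 and 44.3 ± 9.97 CPM (C1qb and Cd68 lower), and neutrophil markers to 25.4 ± 13.6 and 3.84 ± 0.971 CPM (Ltf, Mmp9 and Cxcr2 higher). Sums for B cells were 78.8 ± 12.9 and 71.4 ± 14.9, for T and NK cells 11.7 ± 1.73 and 4.91 ± 1.09 and for mast cells with basophils and eosinophils 7.17 ± 2.7 and 44.6 ± 28.4 CPM.

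Many genes moved the same way in HSC and LMPP. Of the genes called in both comparisons, 144 were higher in both (21.5 expected for independent lists, odds ratio 13.5, Fisher's exact p = 5.97e-85) and 274 lower in both (35.3 expected, odds ratio 25.6, Fisher's exact p = 4.87e-196), with 15 and 6 called in opposite directions (25.2 and 30.1 expected). These make up 47.4% and 64.5% of the HSC calls. Genes are not independent replicates. Without fetal HSC 1 the overlaps were 80 and 101, without fetal HSC 2 they were 65 and 95, and without the 3 libraries that stand apart 592 and 750. Fetal against adult differences correlated across genes at Pearson's r = 0.45 and Spearman's rho = 0.46.

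The interaction asked where the fetal against adult difference itself differs between HSC and LMPP. Pf4 had opposite differences: it was lower in fetal than in adult HSC and higher in fetal than in adult LMPP. It went from 284 to 17.8 CPM in HSC and from 1.04 to 10.2 CPM in LMPP (interaction log2 −7.30 ± 1.19, adjusted p = 0.019). Of 30 megakaryocyte genes 7 had a lower difference in HSC, among them Pf4, Cd9, Mmrn1, Gp1bb, Treml1 and Ppbp (11 lower and 1 higher over the list alone; median −1.97; adjusted p = 2.11e-07, and 0.12 with an estimated correlation). Flt3 went the other way, rising in fetal HSC and falling in fetal LMPP (2.11 ± 0.27, adjusted p = 0.007). Without adult LMPP 1, fetal HSC 1 or fetal HSC 2 the Pf4 call ended (adjusted p = 0.064, 0.077 and 0.17), while that of Flt3 did not end without any single library.

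In all, 80 genes had a higher and 57 a lower difference in HSC than in LMPP, all but 1 of them by at least 2-fold. Leaving out the 3 libraries that stand apart gave 459 and 330, and a term for them 460 and 396. Higher genes numbered 43, 51, 33, 53, 31, 24, 48 and 52 without adult HSC 1, adult HSC 2, adult LMPP 1, adult LMPP 2, fetal HSC 1, fetal HSC 2, fetal LMPP 2 and fetal LMPP 3. Lower genes numbered 31, 14 and 8 without adult LMPP 1, fetal HSC 1 and fetal HSC 2. The largest positive values were those of Slc16a11, Postn, Kmo, an enzyme of tryptophan breakdown, the costimulatory receptor Icos, the leukotriene receptor Cysltr2 and Dach1. Slc16a11 stood at 68.9 ± 10 CPM in adult LMPP and at 0.675, 3.15 and 0.151 CPM in adult HSC, fetal HSC and fetal LMPP. Among the most negative values were those of Cavin2, Evc2, Treml1, Zfp711 and Klhl13. Cavin2, a protein of membrane caveolae, stood at 162 CPM in adult HSC, 20.9 CPM in fetal HSC, 0 in adult LMPP and 7.35 CPM in fetal LMPP. Fitted interactions of genes at 0 in a group depend on the prior count.

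Lymphoid priming genes had a higher difference in HSC (5 called, among them Cnn3, Flt3, Wfdc17 and Satb1; 7 higher and 2 lower over the list alone; median 0.97, or 0.40 at the bound; adjusted p = 0.00133, and 0.12 with an estimated correlation). Cholesterol synthesis genes had a lower one (Idi1 and Sqle called, 5 over the list alone; median −0.80; adjusted p = 2.11e-07, and 0.12 with an estimated correlation). Ribosome biogenesis lay at −0.57 (adjusted p = 7.52e-09, and 0.12 with an estimated correlation), with 0 of 35 genes called by edgeR, 17 at an unadjusted p under 0.05, 6 by DESeq2 and 7 over the list alone. Glycolysis lay at −0.43 (Ldha called; adjusted p = 0.000524, and 0.3 with an estimated correlation). Itgam had a value of 3.11 ± 0.54 (adjusted p = 0.026), a call that ended on leaving out any 1 of 7 libraries, with adjusted p from 0.052 to 0.16. Igf2bp2, Lin28b, Dntt, Vwf, Itga2b, Selp, Hmga2, Procr, Cd48, Hlf, Slamf1, Kit, Ly6a and Mpo did not pass (adjusted p = 0.05, 0.098, 0.11, 0.38, 0.7, 0.54, 0.38, 0.27, 0.22, 0.7, 0.86, 1, 0.98 and 1). Without the 3 libraries that stand apart Igf2bp2, Lin28b, Dntt, Procr and Cd48 passed (0.0021, 0.036, 0.0074, 0.032 and 0.015), and with a term for them the ribosomal protein list was called (median −0.13, 0.027).

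**Figure D3:**
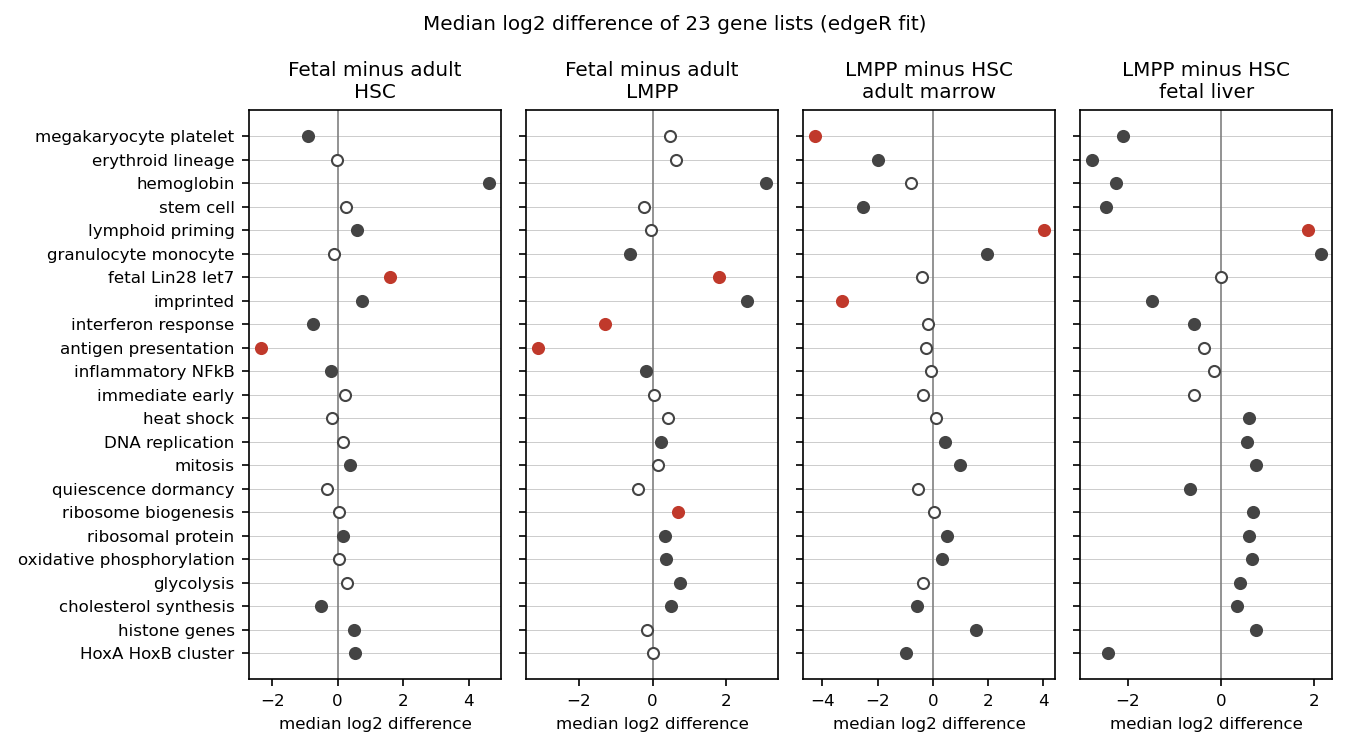
Median log2 difference (x axis) of the 23 gene lists (y axis) in the 4 comparisons of groups, with 1 point per list, red where the list was called also with an estimated correlation, dark where it was called with the preset correlation only and open where it was not called. Antigen presentation lies lowest in both fetal against adult comparisons (−2.35 and −3.12), and the megakaryocyte list lies lowest in adult LMPP against HSC (−4.28).

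LMPP were then set against HSC within the adult marrow (n = 3 and 3), which gives the background of cell type difference. Adult LMPP held lymphoid RNA that adult HSC lacked: Dntt stood at 1350 ± 300 against 0.221 ± 0.356 CPM (log2 12.20 ± 0.97, adjusted p = 0.00011), and Il7r, the interleukin 7 receptor, was at least 207-fold higher (16.7 ± 2.33 CPM against 0). Adult HSC held more megakaryocyte RNA. Pf4 was at 1.04 ± 0.27 CPM in LMPP against 284 ± 218 CPM in HSC (−8.08 ± 0.92, adjusted p = 0.00027) and Vwf at 0.627 ± 0.454 against 123 ± 75.1 CPM. Cavin2 was at 0 in LMPP against 162 ± 58 CPM (at least 1460-fold lower, adjusted p = 2.8e-05).

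In all, 1143 genes were higher and 1373 lower in adult LMPP, 693 and 1165 of them at least 2-fold. With the replicate number as a block in the 6 adult libraries, a fit that takes same-numbered samples as paired, the counts were 2074 and 2282. Such a pairing was not shown. Counts were 2017 and 2291 without the 3 libraries that stand apart, 2271 and 2442 with a term for them, and 727 and 891 without adult LMPP 1. Further large rises were Clec2i, Kcng1, Sema3d and Kmo (at least 355-fold, 322-fold, 164-fold and 162-fold), the lymphocyte receptor Btla (34.6 ± 2.86 against 0.0542 ± 0.0939 CPM) and the chemokine receptor Ccr7 (14.8 ± 1.5 against 0.0217 CPM). Among the further large falls were Evc2, the ephrin Efna1, Rhoj, Treml1, Plscr2, Podxl and P3h2 (at least 220-fold, 212-fold, 187-fold, 185-fold, 183-fold, 141-fold and 137-fold).

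Of 28 lymphoid priming genes 19 rose (23 over the list alone; median 4.01, or 3.42 at the bound; adjusted p = 3.1e-19, and 0.0022 with an estimated correlation). Among them was Cnn3 (289 ± 71.8 against 9.18 ± 2.88 CPM). Flt3 (974 ± 80.7 against 13.4 ± 3.61 CPM), Cd48 (373 ± 42.9 against 5.98 ± 3.41 CPM) and Slamf1 (0.481 ± 0.476 against 70.9 ± 2.69 CPM) are gate genes. Of 30 megakaryocyte genes 25 fell, also over the list alone (median −4.28; adjusted p = 2.34e-14, and 0.038 with an estimated correlation). Among them were Mmrn1 (35.9 ± 7.47 against 770 ± 82.7 CPM), Gng11 (10.3 ± 0.422 against 118 ± 40.7 CPM), Itga2b (10.7 ± 6.1 against 474 ± 251 CPM) and Selp (log2 −2.20). Of 23 imprinted genes 11 fell (16 over the list alone; median −3.30, or −1.75 at the bound; adjusted p = 3.25e-08, and 0.038 with an estimated correlation). Ndn was at 6.13 ± 1.82 against 71 ± 11.9 CPM, the cell cycle inhibitor Cdkn1c at 4.87 ± 0.46 against 71.9 ± 25.3 CPM, and Meg3 at 0.0187 against 12.2 ± 3.74 CPM.

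Of 30 stem cell genes 23 fell (25 fell and 1 rose over the list alone; median −2.52; adjusted p = 6.19e-14, and 0.061 with an estimated correlation). Among them were Mllt3 (13.5 ± 3.2 against 130 ± 31.3 CPM), Ryk (1.68 ± 0.474 against 41.1 ± 2.31 CPM) and Procr (log2 −2.44). Of 21 erythroid genes 9 fell (9 fell and 1 rose over the list alone; median −1.99, or −1.76 at the bound; adjusted p = 1.01e-05, and 0.087 with an estimated correlation). Among them were the transcription factor Gata1 (1.75 ± 0.605 against 107 ± 39.4 CPM), Epor (log2 −6.09) and Aqp1 (−5.82). Granulocyte and monocyte genes rose, 15 of 24 (17 over the list alone; median 1.97; adjusted p = 9.5e-11, and 0.11 with an estimated correlation). Cst7, Plac8 and Emb were up by 5.41, 4.45 and 3.32. Mpo, myeloperoxidase, stood at 2100 ± 255 against 79.9 ± 88 CPM (adjusted p = 0.012), a call that ended without adult HSC 2 (0.054) and with only these groups compared (0.053).

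Mitosis genes rose, 33 of 40 (40 over the list alone; median 1.00; adjusted p = 5.63e-16, and 0.18 with an estimated correlation). Ect2 was at 167 ± 27.9 against 31.7 ± 1.83 CPM, and Kif23 and the cyclin Ccna2 were up by 1.44 and 1.01. Ribosomal protein genes rose, 46 of 54 (52 over the list alone; median 0.52; adjusted p = 2.21e-16, and 0.11 with an estimated correlation). Rps24 and Rps13 were up by 0.74 and Rps9 by 0.62. Of 21 histone genes 14 rose (18 over the list alone; median 1.55; adjusted p = 9.5e-11, and 0.088 with an estimated correlation). Hist2h2ac was at 16 ± 3.36 against 4.74 ± 1.2 CPM. Of 41 DNA replication genes 10 rose (15 over the list alone; median 0.44; adjusted p = 4.92e-06, and 0.29 with an estimated correlation), such as Cdc45 (0.77). Oxidative phosphorylation had 6 rises of 49, also over the list alone (median 0.34; adjusted p = 6.39e-06, and 0.57 with an estimated correlation), led by Ndufa4 (666 ± 193 against 220 ± 43.2 CPM). Cholesterol synthesis had 6 falls of 20, also over the list alone (Sqle −1.13; median −0.56; adjusted p = 0.00326, and 0.2 with an estimated correlation). The DNA replication median was 0.28 without adult HSC 2, and that of oxidative phosphorylation 0.54 without adult HSC 3 and 0.19 without adult LMPP 3.

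The Hoxa and Hoxb genes had 5 falls and 1 rise of 15, also over the list alone (median −0.97; adjusted p = 0.00457, and 0.2 with an estimated correlation). Hoxb5 was at 0.529 ± 0.119 against 10.1 ± 0.834 CPM and Hoxb2 at 1.26 ± 0.708 against 15.4 ± 3.61 CPM. In the fit with the replicate block this list ended above the threshold (adjusted p = 0.059), the only list call that this fit ended. A stricter filter ended it too (0.053), and without the 3 libraries that stand apart the median was −1.48. The call of Hoxb2 ended without adult LMPP 1 (0.053). Hmga2 was higher in LMPP (11.8 ± 3.98 against 2.89 ± 1.28 CPM), Igf2bp2 lower (2.71 ± 0.29 against 15.6 ± 3.89 CPM), and Lin28b was at 0 against 0.379 ± 0.359 CPM (at least 3.41-fold lower). Itgam was higher in LMPP (log2 3.18 ± 0.39, adjusted p = 0.00045), while Kit, Hlf and Ly6a did not pass (adjusted p = 0.37, 0.18 and 0.27), while without the 3 libraries that stand apart Kit and Hlf passed (0.00011 and 0.018), and with the adult block all of them (0.01, 0.015 and 0.02). Among markers of other cells Trf, Ahsg, Pdgfrb and Cd68 were higher and Col1a2, Dlk1, Klf1 and Epb42 lower in adult LMPP. Counting by library totals alone moved the median of all genes from −0.053 to −0.168, with 950 genes higher and 1654 lower.

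Within the fetal liver, LMPP (n = 3) also held lymphoid RNA that HSC (n = 2) lacked. The thymus-homing receptor Ccr9 and the recombinase gene Rag2 were at 63.5 ± 10.5 and 51.1 ± 6.94 CPM in LMPP and at 0 in HSC (at least 664-fold and 535-fold higher, adjusted p = 0.00079 and 0.00071). Fetal HSC held more RNA of the stem cell genes Mllt3 (lower in LMPP, log2 −3.61 ± 0.28) and Procr, at 85.8 ± 19.9 CPM in HSC against 4.88 ± 3.09 CPM in LMPP. Among platelet genes Vwf was at 71.5 ± 10.9 CPM in HSC and 1.51 ± 0.783 CPM in LMPP (log2 −5.52 ± 0.69, adjusted p = 0.00088). Pf4 stood at 17.8 ± 12.1 and 10.2 ± 8.41 CPM and did not pass (adjusted p = 0.5). Dntt was at 0 in LMPP and 0.118 ± 0.167 CPM in HSC (adjusted p = 0.37).

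In all, 1208 genes were higher and 1450 lower in fetal LMPP, 504 and 1258 of them at least 2-fold. Counts were 2579 and 2970 without the 3 libraries that stand apart and 2357 and 2425 with a term for them. They were 342 and 604 without fetal HSC 1, 212 and 386 without fetal HSC 2, and 672 and 884 without fetal LMPP 2. Without fetal LMPP 1, 787 genes were higher. Scaled by library totals alone, 746 were higher and 2161 lower, so that 25.7% of calls were higher against 45.4%, and the median of all genes moved from −0.08 to −0.327. A fit of only these groups called 2103 genes higher, 52.4% of its calls. Other large rises were Gfra1 and Btla (at least 157-fold and 115-fold), Cst7, Atp8b4, Ccr7 and Stc1 (34.7 ± 5.45, 40.2 ± 15.1, 21 ± 1.01 and 29.1 ± 4.98 CPM against 0.0197, 0.0393, 0.0197 and 0.0244 CPM). Large falls were S100a16 (at least 197-fold), Dach1, Slamf1, Trpc6, Gdf3, Pdzk1ip1, Rhag and Cavin1 (log2 −8.27, −8.15, −7.87, −7.02, −6.34, −5.99 and −5.97). Slamf1 and Trpc6 were at 0 in fetal LMPP without fetal LMPP 3, where their fitted values moved by over 1.5 times, like that of Hoxb5.

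Of 28 lymphoid priming genes 16 rose, also over the list alone (median 1.89; adjusted p = 2.29e-11, and 0.014 with an estimated correlation). Flt3 was at 492 ± 21.7 against 29 ± 1.12 CPM, a gate gene like Cd48 (318 ± 69.6 against 16.8 ± 8.2 CPM). Of 30 stem cell genes 26 fell (27 over the list alone; median −2.47; adjusted p = 1.01e-14, and 0.052 with an estimated correlation). Among them was Ctnnal1 (17.6 ± 6.74 against 212 ± 21.2 CPM). Hlf fell by 1.74 (adjusted p = 0.032), a call that ended without fetal HSC 1 (0.073), fetal HSC 2 (0.23), fetal LMPP 1 (0.09) or fetal LMPP 2 (0.098) and with the replicate block (0.094). Megakaryocyte genes had 17 falls and 1 rise, P2ry12 (20 and 2 over the list alone; median −2.10; adjusted p = 2.84e-06, and 0.096 with an estimated correlation). Gng11, Rab27b and Itga2b were down by log2 −3.50, −4.16 and −4.34, and Selp by −3.34. Of 21 erythroid genes 10 fell (11 over the list alone; median −2.78, or −2.68 at the bound; adjusted p = 1.53e-05, and 0.09 with an estimated correlation). Gata1 was at 3.11 ± 1.23 against 49.7 ± 19.1 CPM, and Blvrb and Aqp1 were down (log2 −2.33 and −2.78).

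Hemoglobin genes had 4 falls of 8, all of beta-globin copies, also over the list alone (Hbb-bt 128 ± 73.2 against 633 ± 65.2 CPM; median −2.26; adjusted p = 0.0136, and 0.25 with an estimated correlation), a list call that ended with only these groups compared (0.051). Of 15 Hox genes 10 fell (11 fell and 1 rose over the list alone; median −2.42, or −2.23 at the bound; adjusted p = 3.33e-05, and 0.09 with an estimated correlation), such as Hoxb5 (0.0708 ± 0.123 against 7.15 ± 2.1 CPM) and Hoxb2 (0.494 ± 0.453 against 12.3 ± 0.884 CPM). Of 23 imprinted genes 10 fell (11 over the list alone; median −1.48; adjusted p = 4.36e-07, and 0.052 with an estimated correlation). Igf2 was at 1.55 ± 0.396 against 35.3 ± 6.83 CPM, H19 at 8.2 ± 0.374 against 73.3 ± 13.3 CPM and Meg3 at 0.802 ± 0.491 against 24.8 ± 0.193 CPM. Granulocyte and monocyte genes had 12 rises and 3 falls (15 and 3 over the list alone; median 2.15; adjusted p = 3.33e-05, and 0.25 with an estimated correlation). Plac8 was at 305 ± 62.5 against 26 ± 0.217 CPM and Mpo at 2790 ± 466 against 99.4 ± 2.5 CPM (adjusted p = 0.026). The Mpo call ended without fetal HSC 1 (0.15), fetal HSC 2 (0.19) or fetal LMPP 2 (0.057) and with the replicate block (0.051).

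Growth lists were called in fetal LMPP with the preset correlation. Ribosomal protein genes had 41 rises of 54 (52 over the list alone; median 0.61; adjusted p = 8.83e-18, and 0.09 with an estimated correlation). Rps9 was at 761 ± 40 against 417 ± 8.63 CPM. Oxidative phosphorylation had 28 of 49 (36 over the list alone; median 0.68; adjusted p = 1.75e-13, and 0.26 with an estimated correlation), ribosome biogenesis 18 of 35 (22 over the list alone; median 0.70; adjusted p = 1.54e-10, and 0.052 with an estimated correlation), mitosis 15 of 40 (21 over the list alone; median 0.77; adjusted p = 2.72e-09, and 0.25 with an estimated correlation) and DNA replication 13 of 41 (16 over the list alone; median 0.57; adjusted p = 1.15e-08, and 0.22 with an estimated correlation). Examples were Atp5g3 (0.93), Bop1 (1.03), Npm1 (0.98), Kif23 (0.97), Mcm7 (0.86) and Rrm2 (1.40). Glycolysis had 7 rises and 1 fall of 20 (7 and 2 over the list alone; median 0.41; adjusted p = 0.0196, and 0.29 with an estimated correlation), led by Pgam1 (825 ± 63.6 against 318 ± 18.2 CPM). Heat shock genes had 5 rises of 12 (6 and 1 fall over the list alone; Hspd1 1.14; median 0.60; adjusted p = 0.014, and 0.43 with an estimated correlation). Without fetal HSC 2 the calls of Kif23, Npm1 and Rrm2 ended (0.074, 0.051 and 0.088), and with the replicate block that of the heat shock list (0.072).

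Interferon response genes were split, with 4 rises and 13 falls of 47 (7 and 24 over the list alone; median −0.58; adjusted p = 0.00733, and 0.31 with an estimated correlation): Ifi27 rose (log2 1.33) while Ifi44 and Rsad2 fell (log2 −2.99 and −2.25). Quiescence genes had 3 rises and 5 falls of 22 (3 and 9 over the list alone; median −0.67; adjusted p = 0.0136, and 0.25 with an estimated correlation), with the cell cycle inhibitors going apart, Cdkn1a up by 2.00 and Cdkn1c at 31.5 ± 12.4 against 119 ± 13.5 CPM, and Cyp26b1, which degrades retinoic acid, at 0 against 6.48 ± 0.659 CPM (at least 66.7-fold lower). Histone genes had 1 rise (Hist2h3c2) and 1 fall (Hist1h1c), also over the list alone (median 0.75; adjusted p = 0.00056, and 0.25 with an estimated correlation). Cholesterol synthesis had 1 rise, Fdps (0.99), also over the list alone (median 0.35; adjusted p = 0.014, and 0.25 with an estimated correlation). The call of Hist2h3c2 ended without fetal HSC 1 (0.15), fetal HSC 2 (0.14) or fetal LMPP 1 (0.061), and that of Hist1h1c without fetal HSC 1 (0.064), fetal HSC 2 (0.18), fetal LMPP 2 (0.069) or fetal LMPP 3 (0.051). The calls of Fdps and Cdkn1a ended without fetal HSC 1 (0.057 and 0.054), and those of Fdps and Cdkn1c without fetal HSC 2 (0.1 and 0.051). The quiescence median was −1.08 without fetal LMPP 3, and that of cholesterol synthesis 0.21 without fetal HSC 1. Igf2bp2 was lower in LMPP (117 ± 16.8 against 222 ± 25.1 CPM, adjusted p = 0.019), a call that ended without fetal HSC 1 (0.068), fetal HSC 2 (0.17), fetal LMPP 1 (0.06) or fetal LMPP 2 (0.057). Lin28b, Hmga2, Itgam, Kit and Ly6a did not pass (adjusted p = 0.55, 0.23, 0.93, 0.41 and 0.2), while Hmga2 and Kit passed without the 3 libraries that stand apart (0.0053 and 0.001). The antigen presentation list was not called (adjusted p = 0.0672), but passed with a term for them (median −0.42, 0.014) and by fry (0.0155). Among markers of other cells Pdgfrb was higher, and Cdh5, Col1a2, Slc40a1, Klrb1c, Prg2, Hbb-bs, Hbb-b1, Klf1 and Epb42 were lower in fetal LMPP. The Hbb-b1 call ended without fetal HSC 1 (0.052) or fetal HSC 2 (0.072).

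The cell type difference was compared between ages: 565 genes were higher and 746 lower in LMPP at both (93.8 and 135 expected, odds ratios 19.7 and 21.4), or 49.4% and 54.3% of the adult calls, with 12 and 5 in opposite directions (113 expected for each). Without fetal HSC 1 the overlaps were 248 and 422, without fetal HSC 2 they were 179 and 302, and without the 3 libraries that stand apart 1273 and 1444. Differences correlated across genes at r = 0.60 and rho = 0.62.

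Open chromatin was set beside these differences. The fetal HSC list held 48286 distinct peaks over 31.0 Mb, that of adult HSC 53068 over 33.3 Mb, that of fetal LMPP 37156 over 24.7 Mb and that of adult LMPP 50579 over 32.1 Mb, with median widths of 563, 563, 580 and 567 bp and median signal values of 7.51, 9.8, 5.62 and 8.11. Merged, they gave 77133 regions, of which 23657 (30.7%) lay in all 4 lists. Between fetal and adult HSC 35722 of 64487 regions (55.4%) were shared, with 12149 in the fetal and 16616 in the adult list only. Between fetal and adult LMPP 30544 of 56384 (54.2%) were shared, with 6189 and 19651 in 1 list only. In adult marrow 35433 of 67059 regions (52.8%) were shared by LMPP and HSC, with 14748 and 16878 in the LMPP or HSC list only, and in fetal liver 28916 of 55714 (51.9%), with 7801 and 18997. Lists differ in length, so the numbers of regions in 1 list only are not compared between lists. A region missing from a list was not called there, which is not a test of a difference.

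**Figure D4:**
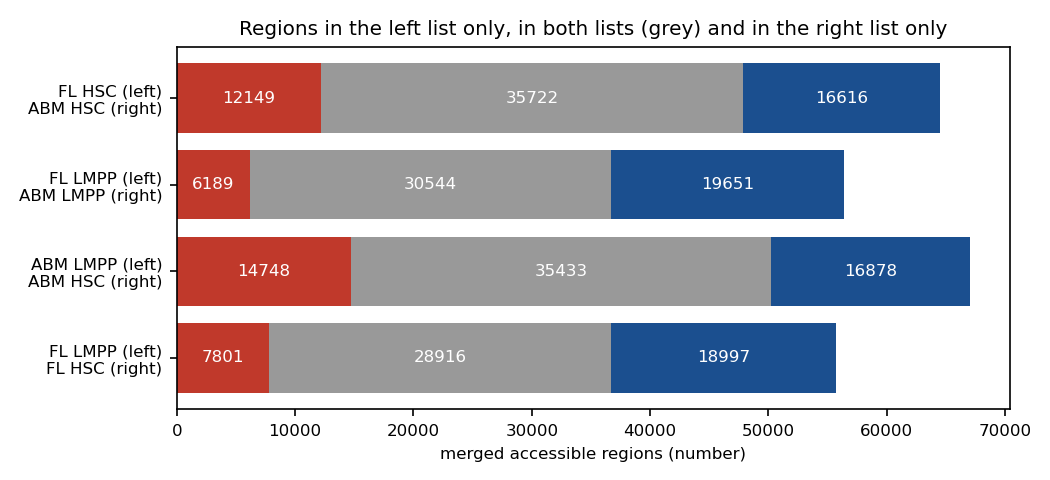
Number of merged accessible regions (x axis) in each comparison of 2 peak lists (y axis), as stacked bars for regions in the first list only (red), in both lists (grey) and in the second list only (blue). Shared regions make up 55.4%, 54.2%, 52.8% and 51.9% of the 4 bars.

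Regions in 1 list only lay away from promoters: 7.56% of fetal-only and 7.91% of adult-only HSC regions were within 1000 bp of a start site, against 33.4% of shared regions (odds ratios 0.163 and 0.171). For LMPP the shares were 11.9% and 8.73% against 35.0%, for adult LMPP and HSC 5.73% and 9.85% against 32.8%, and for fetal LMPP and HSC 6.99% and 10.2% against 37.6%. Of genes higher in fetal HSC 44.6% (121 of 271) had a fetal-only region, against 25.5% of genes not called (odds ratio 2.36, Fisher's exact p = 2.09e-11) and 26.5% of genes lower in fetal HSC. Of genes higher in adult HSC 62.6% (243 of 388) had an adult-only region, against 38.0% (odds ratio 2.73, Fisher's exact p = 7.45e-22) and 50.9% of genes higher in fetal HSC (odds ratio 1.62, Fisher's exact p = 0.00303). Genes higher in adult LMPP had an adult-only region in 60.1% against 44.0% (odds ratio 1.91, Fisher's exact p = 1.18e-23), and genes higher in fetal LMPP in 41.4%. For genes higher in fetal LMPP the shares were 20.1% against 16.6% (odds ratio 1.26, Fisher's exact p = 0.00824), and genes of the opposite direction had one in 17.8% (odds ratio 1.16, Fisher's exact p = 0.204). This last contrast depends on the setting: odds ratios were 1.53 within 10000 bp (Fisher's exact p = 0.00589), 1.21 within 100000 bp (0.0885) and 1.92 with the upper 50% of each list by q (0.000258). LMPP against HSC gave 48.9% against 33.3% and 59.8% against 36.2% in the adult (odds ratios 1.92 and 2.61), and 29.1% against 21.6% and 55.0% against 41.0% in the fetus (1.49 and 1.76), with 34.8%, 37.7%, 22.4% and 37.1% for genes of the opposite direction.

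At named genes, the promoter of Igf2bp1 (chromosome 11, 96005498 to 96007861) lay in both fetal lists and in neither adult list, with signal values of 4.63 and 2.91 in fetal HSC and LMPP. The promoter of Lin28b (chromosome 10, 45469054 to 45470639) lay in all 4 lists, and further regions near it (45453990 to 45454431 and 45473680 to 45473972) lay in the fetal LMPP list only. A region 24186 bp from the start of Aldh1a1 (chromosome 19, 20467745 to 20468397) lay in the adult lists only. So did both regions of Selp, whose RNA did not pass by age. Against their RNA, of regions near Hmga2 and Postn, higher in fetal HSC, 2 and 3 lay in adult and 1 each in fetal lists only. Of those near Aspa, higher in adult HSC, 1 lay in fetal and 0 in adult lists only. Start-site regions of Pf4 (chromosome 5, 90771757 to 90772797) and Vwf (chromosome 6, 125552662 to 125553322) lay in both HSC lists and in neither LMPP list. The fetal LMPP list held 0 of the 4 regions of Pf4 and the adult LMPP list 2 (1 at 707 bp from the start), against the RNA. A region near the start of Dntt (chromosome 19, 41030876 to 41031703) and the start site of Flt3 (chromosome 5, 147399861 to 147400786) lay in all 4 lists.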

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

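The results in this part are the genes and lists whose fetal against adult difference in HSC differed from that in LMPP by the interaction test, and the tests of the megakaryocyte and hemoglobin patterns were chosen after their results were seen, while those of the 3 libraries that stand apart and of the other splits were not.

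The megakaryocyte list had a median interaction of −1.97 on the log2 scale (adjusted p = 0.12 with an estimated correlation), with Pf4 at −7.30 and Treml1 at −9.57. Without the 3 libraries that stand apart the list median was −1.64 (camera adjusted p = 9.2e-05), which argues against these libraries as its cause, and the adult LMPP minus adult HSC median of −4.28 argues against free platelet RNA in the marrow suspension, which would reach both adult sorts. Platelets or megakaryocytes held to adult HSC cannot be told apart from expression by the HSC, since Ppbp, abundant in platelets, averaged 7.54 ± 3.37 CPM in adult HSC beside 284 CPM for Pf4 and no pure platelet library sets the ratio. Accessible regions near the list's genes gave an odds ratio of 0.956 for fetal against adult HSC, which decides nothing. A difference of age and tissue stays open, untested.

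Hemoglobin genes had a median interaction of 1.46 (1.68 at the bound), with 0 of 8 genes called by edgeR, 4 at an unadjusted p under 0.05 and 2 by DESeq2. The list did not pass by fry (adjusted p = 0.17), and its call ended with an estimated correlation (0.36), with DESeq2 (0.075), without adult HSC 2 (0.053) and without fetal HSC 1 (median 0.96, 0.054). The ratio of Hba-a1 to Hbb-bt, at most 0.0248 in fetal HSC and at least 0.0857 in fetal LMPP, cannot test a common erythroid source. Hba-a1 overlapped by age (2.36 to 38.4 CPM adult, 8.58 to 54.7 CPM fetal), so Hbb-bt mostly set the ratio. A common or separate source, shared beta-globin reads and age or tissue stay open, untested.

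Adult HSC 3, adult LMPP 3 and fetal LMPP 1 deviated together from their groups, with deviations correlated at 0.47, 0.29 and 0.28, and a term for them called 5937 genes. Thinned to the lowest library total the term still called 5727 genes, which argues against depth. With the trend on transcript length removed from each library it called 3765 (63.4%), which argues against that trend as the whole cause. The labels give no batch for these libraries, and no biological explanation was tested.

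Among the other genes with a difference between HSC and LMPP by the interaction test, the fitted values, which depend on the prior count where a group is at 0, were 10.91 for Slc16a11, 10.83 for Postn, 9.30 for Kmo, 8.11 for Icos, 6.98 for Cysltr2, 5.95 for Dach1, 3.11 for Itgam and 2.11 for Flt3. Negative values were −13.95 for Cavin2, −11.69 for Evc2, −9.08 for Zfp711 and −7.82 for Klhl13. The call of Klhl13 ended without fetal HSC 1 (adjusted p = 0.085) or fetal HSC 2 (0.14), and that of Treml1 without fetal HSC 2 (0.067). That of Dach1 ended without adult HSC 1 (0.061), adult HSC 2 (0.068), adult LMPP 1 (0.081), adult LMPP 2 (0.064), fetal HSC 1 (0.11), fetal HSC 2 (0.14), fetal LMPP 1 (0.077) or fetal LMPP 2 (0.07). With the replicate block the calls of Dach1 (0.072), Itgam (0.096) and Cysltr2 (0.051) ended. Among the lists, medians were 0.97 for lymphoid priming, 0.71 for Hox genes, 0.67 for histone genes, 0.37 for interferon response, 0.35 for granulocytes and monocytes, 0.35 for antigen presentation and 0.22 for mitosis. They were −0.80 for cholesterol synthesis, −0.57 for ribosome biogenesis, −0.54 for heat shock, −0.49 for the Lin28b and let-7 list, −0.43 for glycolysis and −0.36 for oxidative phosphorylation. With an estimated correlation, 0 of the 15 list calls held.

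Leaving out 1 library ended or moved several of these list values. Mitosis had a median of 0 without adult HSC 2 (adjusted p = 0.44) or fetal HSC 1 (0.59), 0.03 without adult LMPP 3 (0.25) and 0.12 without fetal LMPP 3 (0.12), and 0.34, 0.36 and 0.36 without adult HSC 3, adult LMPP 2 and fetal HSC 2. Granulocytes and monocytes had 0.07 without adult HSC 1 (0.46), 0.34 without adult HSC 2 (0.06), 0.26 without adult LMPP 3 (0.055) and 0.11 without fetal HSC 2 (0.1), 1.09 without adult HSC 3 and 0.58 without fetal HSC 1, and the call ended with DESeq2 (0.075). Antigen presentation had 0.27 without adult HSC 1 (0.12), 0.39 without adult HSC 2 (0.058), 0.22 without adult LMPP 3 (0.18), 0.28 without fetal HSC 2 (0.082), 0.33 without fetal LMPP 2 (0.088) and 0.60 without fetal LMPP 3. The Lin28b and let-7 list had −0.26 without adult HSC 2 (0.069), −0.26 without adult LMPP 3 (0.11), −0.51 without fetal HSC 1 (0.062), −0.44 without fetal LMPP 2 (0.059), −0.37 without fetal LMPP 3 (0.054) and −0.75 without adult LMPP 2, and ended without a filter (0.061). Heat shock had −0.20 without adult HSC 3 (0.11) and −0.40 without adult LMPP 1 (0.051), and ended with the term for the 3 libraries that stand apart (0.05). Values that moved without losing the call were oxidative phosphorylation (−0.14 without adult HSC 3 and −0.22 without adult LMPP 2), Hox genes (0.41 and 0.45 without fetal HSC 2 and fetal LMPP 2, and over 2 times the value without fetal LMPP 1) and lymphoid priming (0.26 without fetal HSC 2).

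Other splits of the same 6 libraries were counted for the comparisons with 3 libraries in each group. For fetal against adult LMPP the real split called 1959 genes and the other 9 splits at most 0 by edgeR (33 to 974 at an unadjusted p under 0.05, and 0 to 16 by DESeq2), so 1 of 10 splits called as many. For adult LMPP against HSC the real split called 1798 and the others at most 0 (12 to 2266 unadjusted, and 0 to 326 by DESeq2), so again 1 of 10. There the highest was 0 both among other splits that part all same-numbered pairs and among the rest. With 10 splits no share under 0.05 can be reached.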

How the results depend on the processing

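The fits without the 3 libraries that stand apart, with a term for them, and of adult libraries with a replicate block were chosen after seeing the data, and the other alternatives were planned. No called value of a gene or list changed sign, while the balance of higher and lower counts did in some fits. Comparing only the groups in question gave 196 genes higher in fetal HSC, 701 higher in adult LMPP than HSC, 2103 higher in fetal LMPP than HSC and 91 in the overlap of higher genes. DESeq2 called 657 and 903 genes for fetal against adult HSC, 1607 and 1840 for LMPP, 370 and 301 for the interaction, and overlaps of 309 and 550. Library totals alone gave 746 higher in fetal LMPP than HSC and 122 higher for the interaction. The replicate block over all groups gave 45 higher for the interaction, and in adult libraries 2074 and 2282 genes for LMPP against HSC, and the block moved no other count past 1.5 times. With the term, counts were 956 and 967, 2666 and 2319, 2271 and 2442, 2357 and 2425, and 460 and 396 for the interaction, with overlaps of 542, 647, 1268 and 1332. Without the 3 libraries they were 1096 and 1241, 2195 and 2215, 2017 and 2291, 2579 and 2970, and 459 and 330, with overlaps of 592, 750, 1273 and 1444. The cause of these shifts was not tested. Leaving out each library in turn gave 104 to 327 and 109 to 384 genes for HSC, 562 to 854 and 749 to 1168 for LMPP, 727 to 1506 and 891 to 1591 for adult LMPP against HSC, 212 to 899 and 386 to 1219 for fetal LMPP against HSC, 24 to 104 and 8 to 66 for the interaction, and overlaps of 65 to 161, 95 to 263, 179 to 682 and 302 to 768. The lowest counts came without fetal HSC 2 wherever fetal HSC took part and without adult LMPP 1 or fetal LMPP 2 elsewhere. A lone fetal HSC library was taken to vary like other groups. Shared accessible regions moved from 55.4%, 54.2%, 52.8% and 51.9% to 60.8%, 58.2%, 54.9% and 55.6% in the upper 50% of each list by q, and to 58.3%, 56.7%, 54.1% and 54.3% with lists of equal length. Over all alternatives, values of named genes that were called kept their call in 3799 cases and lost it in 162, and list calls in 1231 and 124, of which 63 were lost with an estimated correlation. The motif test was not run. Fitted values of genes at 0 in a group depend on the prior count, and bounds for them on depth. Fry, which tests a list against no change and not against other genes, did not pass for the called lists of mitosis, ribosomal protein, histone and Hox genes for HSC, of granulocytes and monocytes and oxidative phosphorylation for LMPP, of oxidative phosphorylation in adult and heat shock in fetal LMPP against HSC, and of 10 lists for the interaction. It passed for lists not called: megakaryocytes for LMPP, the Lin28b and let-7 list and quiescence in adult LMPP against HSC (0.0111 and 0.000545) and antigen presentation in fetal LMPP against HSC.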

Other observations

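The tests of accessible regions in this part were chosen after the gene results were seen.

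Regions near genes of the 23 lists were tested in every comparison, adjusted within each. Only the first result given for each list below passed. In LMPP, 11 of 21 regions in 1 list only near Lin28b and let-7 genes (52.4%) were fetal and 10 adult. Near other genes 20.7% were fetal (odds ratio 4.21, Fisher's exact p = 0.00134, adjusted p = 0.0309). In HSC the odds ratio was 2.83 (Fisher's exact p = 0.0152, adjusted p = 0.35). Near granulocyte and monocyte genes, 29 regions lay in the adult LMPP and 8 in the adult HSC list only (78.4% against 47.9% near other genes, odds ratio 3.95, Fisher's exact p = 0.000203, adjusted p = 0.00467). In fetal cells the odds ratio was 1.91 (Fisher's exact p = 0.0848, adjusted p = 0.487). Regions near a gene are not independent replicates, and each group has 1 list.

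Alb, an abundant liver transcript, was at 0 CPM in all adult libraries and at 13.7 CPM in fetal HSC 2 and 13.2 CPM in fetal LMPP 1. Prss34, a basophil protease gene, was at 96.2 CPM in adult HSC 3 and 39.3 CPM in adult LMPP 3, and Prg2, an eosinophil granule gene, was at 31 CPM in fetal HSC 2.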
